A study of Nothobranchius furzeri with 15 samples.

How the data were processed

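Ribosome-depleted total RNA was sequenced from brain and muscle of the African turquoise killifish Nothobranchius furzeri, strain GRZ-AD, an annual fish kept as a model of vertebrate ageing. The labels give 3 ages: 3.5, 8.5 and 14 weeks. The authors' deposited comparisons name these ages young, adult and old. Brain has 3 libraries per age and muscle has 2, which makes 15 libraries. Per the labels' protocols, tissues were dissected and frozen, RNA was extracted with Trizol, ribosomal RNA was removed with a kit made for mammals, and stranded libraries were read as paired ends on an Illumina HiSeq.

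Circular RNAs (circRNAs) are closed loops made when the end of an exon is joined to the start of an upstream exon; a read across that back-splice junction marks the loop. The authors deposited raw counts of circular junction reads and, for the same positions, raw counts of linear reads, 1 column per library and 1810 circRNAs. Per the submitters' processing notes, STAR 2.5.2b was used, and per the file headers the columns come from its chimeric junction output. The caller of circular junctions, the genome build, the annotation and the definition of the linear count are not given in the sources used here. A table deposited by the authors gives each position, strand, host gene and whether each end lies in an annotated exon, with a junction type of 1 for 1799 circRNAs and 2 for 11. For 4 comparisons of neighbouring ages within a tissue, the authors deposited p-values from a test named bbTest per the file headers; they are not labelled as adjusted. The deposited count tables held 0 columns of other samples.

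Libraries held 1343 to 4400 circular reads and 76515 to 135698 linear reads. With a median of 10 reads per detected circRNA over all libraries, most single circRNAs are measured with wide counting error. Intervals (exact binomial at 95%) and floors (3 counts over a group) cover counting error only; folds from counts use the library sizes of the fit, and the fold of a share uses the shares. The labels do not say that libraries came from separate animals, so p-values measure the spread between these samples, which may be technical. No pair of replicate libraries was identical or agreed within sampling noise, and each counted as 1 replicate.

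CircRNAs are named by the host's symbol, with a number where a host has more than 1, in the order of the table; "unannotated" marks those with no host. Of 1262 host genes, 705 had a name in the file, 339 took one from a RefSeq gene table of assembly NfurGRZ-RIMD1, used for names alone, and 218 kept their identifier. Coordinates are the files' own.

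Circular reads were tested with edgeR 4.0.16 quasi-likelihood F tests with Benjamini-Hochberg adjustment at 0.05, for circRNAs with 10 or more circular reads over the libraries compared. Library sizes and TMM factors came from the linear counts, so that a rise of all circRNAs together is not normalized away. All ages of a tissue shared 1 fit. The circular share of a circRNA was tested in edgeR with circular and linear counts as paired columns of each library; the tested value is the log2 change of the circular to linear ratio. Abundances are printed as CPM, circular reads scaled to the linear library size, and host levels as CPM of the linear reads. Printed shares are 100 times circular reads over circular plus linear reads. Brain and muscle were compared in 1 fit over 15 libraries as the mean difference over the 3 ages, and an interaction term tested whether the change from 3.5 to 14 weeks differed between tissues. Linear counts were also summed per host gene and tested between 14 and 3.5 weeks. Total shares and numbers of detected circRNAs, after thinning to the smallest library of the tissue, were tested with two-sided exact permutation tests. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, where 5 or more circRNAs of a list were tested. Camera compares a list with the other circRNAs tested, so it cannot show that a list did not move.

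Before the data were examined, the tests, the alternatives, 17 gene lists and a rule for the genes named were fixed; 16 lists had a circRNA in the table, and the cell cycle list had none. The rule takes the 10 most abundant circRNAs of each tissue and the 5 hosts with the most circRNAs. It takes up to 10 circRNAs per direction past the threshold by size of change, or the 5 smallest p where fewer than 3 passed. It also takes up to 4 members per list with the most reads and the 5 smallest adjusted p of each deposited comparison. Lists matched symbols in any case, with a trailing paralog letter removed, so that the titin symbols ttn.1 and ttn.2, which carry a number, are in none.

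Alternatives were TMM of the circular counts, DESeq2 size factors, DESeq2 1.42.0, no filter, a minimum of 30 reads, a beta-binomial test of the share, each library left out, and the replicate number as a block. A fit without brain libraries 2 and 3 of 3.5 weeks, a tissue fit on linear totals without TMM, total shares without the positions with the most linear reads, the gene lists at 8.5 against 3.5 weeks and tests of pairs of ages were added after seeing the data. On simulated counts, the edgeR test of abundance was run on 533 brain circRNAs (14 against 3.5 weeks). It recovered 2% of 2-fold, 19.0% of 4-fold and 48.1% of 8-fold changes, with 2.56% of calls false. Of 4-fold and 8-fold changes it recovered 9.38% and 30% among 253 in muscle (8.5 against 3.5 weeks), and 32.7% and 80% among 721 between tissues. The edgeR test of the share recovered fewer: 6.90% and 29.6% in brain, 3.33% and 16.7% in muscle, and 10.2% and 72.5% between tissues. The simulated groups shared a common mean profile and a fixed dispersion. The recovery between tissues therefore does not cover the difference in composition between real brain and muscle. The beta-binomial test gave p under 0.05 for 8.36% of unchanged circRNAs in brain, 12.2% in muscle and 10.3% between tissues. Summed host counts recovered 44.8% of 2-fold changes among 1232 brain hosts. R 4.3.3, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.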

Results

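Circular and linear reads were counted at 1810 circRNAs in brain and muscle of turquoise killifish aged 3.5, 8.5 and 14 weeks, with 3 brain and 2 muscle libraries per age. Brain libraries held 2095 to 4400 circular reads and muscle libraries 1343 to 4269. At least 1 circular read was found for 1673 circRNAs: 786 in brain alone, 140 in muscle alone and 747 in both, while 137 of the listed circRNAs had 0 reads. The circRNAs came from 1262 host genes, 987 of them with 1 circRNA and 27 with 4 or more. Both ends lay in annotated exons for 1464 (80.9%), and the median distance between the ends was 5096.5 bp (quartiles 1884 and 11683.8).

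In brain, the most abundant circRNA came from LOC107387794 on chromosome 16 (23317792 to 23319303, both ends exonic), with 676 ± 84.5 CPM (SD, n = 9). Circular reads made up 82.2% ± 4.57 of the reads at its position. It was followed by circRNAs of bace1, the beta-secretase that cleaves amyloid precursor protein (chromosome 7, 4261005 to 4288732; 564 ± 140 CPM), and of klc1, a kinesin light chain (chromosome 18, 4797685 to 4805789; 533 ± 115). The circRNA of eif3l, a subunit of translation initiation factor eIF3 (chromosome 6, 4671792 to 4688940), reached 427 CPM and that of oxr1, an oxidation resistance gene, 396. For bace1, klc1, eif3l and oxr1, 1 end of the circRNA lay outside annotated exons. The other circRNAs among the 10 most abundant, LOC107395747, LOC107376304, nsun4.1, LOC107390307.1 and LOC107376911, lay between 369 and 255 CPM. This brain order is of the mean over the ages. The circRNA of oxr1 was above that of eif3l at 8.5 weeks (423 and 408) and at 14 weeks (480 and 355). At 8.5 weeks LOC107395747 reached 524, and at 3.5 weeks klc1 (576) was above bace1 (530). The host genes with the most detected circRNAs in brain were si:ch211-186j3.6 with 7, grm8b, a metabotropic glutamate receptor, with 6, and grin2da, an NMDA receptor subunit, adgrb2, nbeab and cntn5 with 5 each.

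Muscle was led by the circRNA flnc.2 of filamin C, an actin cross-linker of striated muscle (chromosome 2, 1030947 to 1031338), with 2091 ± 421 CPM (SD, n = 6) and a circular share of 47.9% ± 3.33. The circRNA ttn.1 of titin, the giant spring protein of the sarcomere (chromosome 10, 31623386 to 31628418), followed with 784 ± 220 CPM and a share of 2.17%. The circRNAs eif3l (509 CPM), nsun4.1 (394) and ryr1b (382), the last from the calcium release channel of the sarcoplasmic reticulum, came next, then filip1l.2, cap2.2, mylk4a.1, cox4i2.2 and gulp1 between 381 and 277. This order is of the mean over the 3 ages: at 8.5 weeks nsun4.1 (634), ryr1b (578) and gulp1 (535) were at or above eif3l (533), and at 3.5 weeks filip1l.2 (667) was above eif3l (588). At 14 weeks cap2.2 (437) was above eif3l (407). The 10 most abundant circRNAs held 26.1% of circular reads in muscle and 15.2% in brain. The hosts flnc, LOC107394000, nisch, scn4aa, ttn.2 and adgrl2 had 4 detected circRNAs each in muscle.

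The share of circular reads in all reads counted addressed whether circRNAs as a class become more abundant with age. In brain it was 2.31% ± 0.0802 at 3.5 weeks, 3.06% ± 0.455 at 8.5 weeks and 2.84% ± 0.345 at 14 weeks (SD, n = 3 each). In muscle it was 1.38% ± 0.00829, 3.28% ± 0.138 and 2.16% ± 0.448 (SD, n = 2 each). The slope over age did not pass in brain (0.0485 percentage points per week, two-sided exact permutation p = 0.160, adjusted 0.267 over 5 such tests). It did not pass in muscle either (0.0699 per week, exact permutation p = 0.367, adjusted 0.458), where it was 0.0272 without library 1 and 0.0282 without library 3 of 3.5 weeks and 0.137 without library 1 of 14 weeks. The smallest p possible were 0.00119 and 0.0222. The difference of 8.5 from 3.5 weeks was 0.742 points in brain (exact permutation p = 0.1) and 1.90 points in muscle (exact p = 0.333), both the smallest p that 3 against 3 and 2 against 2 libraries allow. After thinning to equal totals, 624 ± 4.60, 663 ± 36.8 and 638 ± 33.1 circRNAs were detected in brain at the 3 ages, and 243 ± 28.7, 362 ± 27.4 and 373 ± 10.4 in muscle. Neither trend passed (brain 1.19 per week, exact permutation p = 0.609, adjusted 0.609; muscle 12.1 per week, exact p = 0.0667, adjusted 0.167). The brain slope ranged from 0.0610 without library 1 of 14 weeks to 3.00 without library 3 of 14 weeks, and was -0.227 without libraries 2 and 3 of 3.5 weeks. Brain exceeded muscle by 0.460 points (exact permutation p = 0.048, adjusted 0.167), and by 0.281 to 0.681 with 1 library left out (0.281 and 0.283 without muscle library 1 or 3 of 3.5 weeks, 0.681 without muscle library 1 of 8.5 weeks). Averaged over the ages, that range was 0.355 to 0.566. The difference was -0.478 (exact permutation p = 0.165) without the positions among the 10 with the most linear reads in either tissue, and -0.288 (exact permutation p = 0.359) when each tissue lost its own 10.

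**Figure D1:**
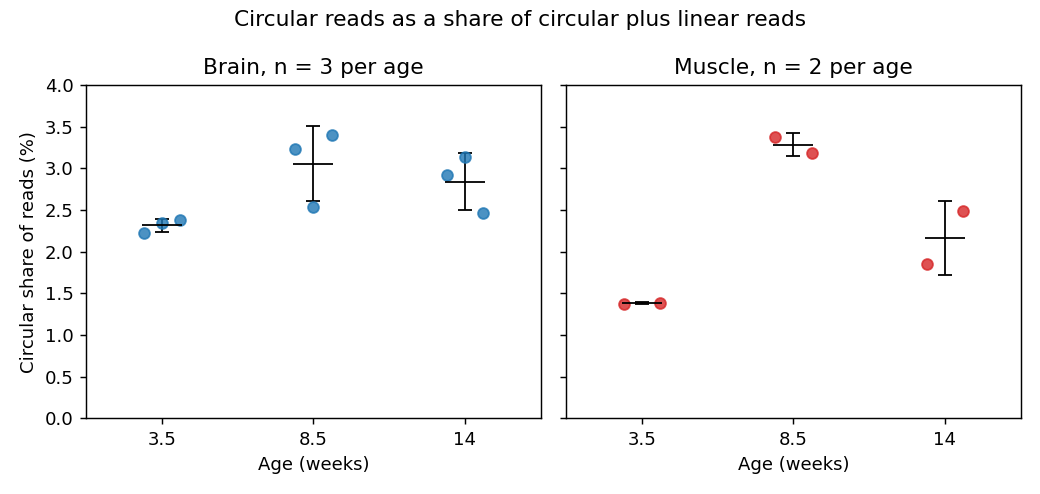
Circular share of all reads counted (percent, y axis) against age in weeks (x axis) for brain and muscle, with 1 point per library and the mean with SD as bars (brain n = 3, muscle n = 2 per age). The muscle libraries of 8.5 weeks sit at 3.38% and 3.18%, above those of 3.5 weeks at 1.38% and 1.39%, and the brain libraries of 3.5 weeks lie between 2.22% and 2.38%.

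In brain, the circRNA of gabra6b, a GABA-A receptor subunit (chromosome 15, 23754773 to 23755793, both ends exonic), rose between 3.5 and 8.5 weeks. It went from 5 reads to 43 over 3 libraries each (log2 change 3.21, SE 0.74, adjusted p = 0.00871). It was at 30 reads at 14 weeks, and the linear reads at its position went from 488 to 611 and 627. Between 3.5 and 14 weeks the circRNA of lmnb2, which encodes lamin B2 of the nuclear lamina (chromosome 16, 35741602 to 35745989, both ends exonic), rose from 5 reads to 48 (log2 change 2.95, SE 0.74, adjusted p = 0.0440). Its linear reads went from 275 to 223. Both were seen in each of the 3 older libraries and in 2 of the 3 at 3.5 weeks, with uneven counts. In libraries 1, 2 and 3, gabra6b had 1, 0 and 4 reads at 3.5 weeks and 26, 14 and 3 at 8.5 weeks. For lmnb2 the counts were 0, 1 and 4 at 3.5 weeks and 9, 32 and 7 at 14 weeks. CircRNAs with the next smallest p did not pass. LOC107395747 was at 70 reads at 3.5 weeks and 161 at 8.5 weeks (log2 1.29, SE 0.35, adjusted p = 0.0772). The circRNA enpp6.2, from a choline phosphodiesterase of oligodendrocytes, was at 40 and 95 (log2 1.34, adjusted p = 0.167). At 14 weeks cnksr2.1, from a synaptic scaffold gene, had 30 reads against 3 at 3.5 weeks (ratio 8.90, counting interval 2.77 to 45.6, adjusted p = 0.200), and kitlga.2 had 18 against 0 (at least 5.34-fold, adjusted p = 0.200).

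Of 639 brain circRNAs tested, 1 rose at 8.5 against 3.5 weeks (60 had an unadjusted p under 0.05), none changed at 14 against 8.5 weeks (31 unadjusted, DESeq2 also 0) and 1 rose at 14 against 3.5 weeks (63 unadjusted, DESeq2 0). The median log2 change was 0.47, -0.19 and 0.34, and the first was 0.12 with TMM of the circular counts, under which neither call remained. For the circular share, edgeR called none of 638 at any of the 3 steps (42, 35 and 52 unadjusted), and neither did the beta-binomial test. A test of any difference among the 3 ages called 1 for abundance, gabra6b (adjusted p = 0.0497), and none for the share (47 unadjusted). The gabra6b call in that test was lost with DESeq2, with DESeq2 size factors, with TMM of the circular counts, with no filter, with a minimum of 30 reads and with the replicate block. It was also lost without library 1 or 2 of 3.5 weeks or 1 or 2 of 8.5 weeks. With 1 library left out there were 0 to 4 calls at 8.5 against 3.5 weeks, with 4 without library 3 of 3.5 weeks, and 0 to 1 at 14 against 3.5 weeks. The gabra6b call at 8.5 weeks was lost without library 1 or 2 of 3.5 weeks or library 1 or 2 of 8.5 weeks (adjusted p 0.0532 to 0.422). The lmnb2 call was lost without library 1 or 2 of 3.5 weeks, 2 of 8.5 weeks or 2 of 14 weeks (0.0766 to 0.587). With the replicate block neither of these calls remained, and with no filter the lmnb2 call was lost. The change from 3.5 to 14 weeks was not shown to differ from that in muscle for lmnb2 (interaction adjusted p = 0.784) or any other circRNA. The interaction called 0 of 896 for abundance (49 unadjusted, 0 by DESeq2, smallest adjusted p 0.0863) and 0 of 893 for the share (23 unadjusted, 0 by the beta-binomial test).

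Neuronal gene groups held most of the listed brain circRNAs, and none passed as a group against the other circRNAs between 3.5 and 14 weeks. Of 35 circRNAs of postsynaptic receptors and scaffolds, 28 of axon guidance and cell adhesion genes and 12 of ion channels, 0 passed over all tested and 0 adjusted over the list alone. Of 7 from active zone and synaptic vesicle genes, 0 passed over all and 1 adjusted over the list alone, syn3.2 of a synapsin (0 reads at 3.5 weeks, 2 at 8.5 and 15 at 14, at least 4.45-fold). Of 3 from oligodendrocyte genes, 0 passed over all and 1 over the list alone, enpp6.2. Counts were 0 on both scales for cytoskeleton and motors (12), known mammalian circRNA hosts (7), chromatin regulators (6), ubiquitin ligases (6), sarcomere (3), and lists of 1 or 2. The smallest camera adjusted p among the lists with 5 or more was 0.942. For the postsynaptic, ion channel and cytoskeleton lists the median and mean were above 0 and the test pointed down, and for mammalian hosts the median was below 0 with the mean and test above. Camera called no list at 8.5 against 3.5 weeks either (smallest adjusted p 0.318).

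In muscle, 4 circRNAs rose between 3.5 and 8.5 weeks. The circRNA gulp1, from an engulfment adaptor gene (chromosome 9, 3411254 to 3411821), rose from 4 reads to 138 and reached 535 ± 80.9 CPM (SD, n = 2; log2 change 4.50, SE 0.84, adjusted p = 0.0173). The circRNA cap2.2, from an actin regulator of striated muscle (chromosome 12, 15085283 to 15089623), rose from 30.5 ± 29.4 to 506 ± 2.23 (log2 4.10, SE 0.70, adjusted p = 0.0145). The circRNA atp2a1.3, from the fast-twitch calcium pump of the sarcoplasmic reticulum (chromosome 6, 42628533 to 42633424), had 71 reads at 8.5 weeks against 3 at 3.5 weeks (ratio 16.9, counting interval 5.55 to 83.8, adjusted p = 0.0448). A circRNA with no host on the same chromosome (38382734 to 38404700) rose from 15 reads to 124 (log2 2.56, SE 0.57, adjusted p = 0.0448). All 4 were higher in both libraries of 8.5 weeks. Linear reads at the same positions went from 10 to 90 (gulp1), 594 to 954 (cap2.2), 1856 to 3777 (atp2a1.3) and 105 to 267 (the circRNA with no host). The circular share did not pass in edgeR for gulp1 (log2 1.94, adjusted p = 0.494) or the circRNA with no host (log2 1.70, adjusted p = 0.420). At 14 weeks, cap2.2 stayed above its level of 3.5 weeks with 437 ± 76.2 CPM (log2 3.89, SE 0.71, adjusted p = 0.0264). That call was lost without library 1 or 3 of 8.5 weeks (adjusted p = 0.236 and 0.652) or 1 or 2 of 14 weeks (0.0839 and 0.581). At that age gulp1 at 272 ± 222 did not pass (log2 3.50, adjusted p = 0.183), nor did atp2a1.3 with 28 reads (adjusted p = 0.422).

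As a share of the reads at its position, the circRNA of ak1, an adenylate kinase of muscle (chromosome 8, 24220445 to 24222420), rose at 8.5 weeks. It had 18 circular reads against 0 at 3.5 weeks (share at least 5.59-fold higher, adjusted p = 0.0160) beside 14290 and 13324 linear reads; 0 of 13324 allows a share of up to 0.0225%. The call was lost without library 3 of 3.5 weeks, 1 of 8.5 weeks or 3 of 8.5 weeks (adjusted p = 0.124, 0.223 and 0.518) and with no filter on reads (0.923). Close to the threshold were cap2.2 and neb.2, the latter of nebulin (adjusted p = 0.0620 each), and atp2a1.3 and myom2b, the latter of an M-band protein (0.0824 each). Of 292 muscle circRNAs, 4 rose at 8.5 against 3.5 weeks (52 unadjusted), 0 changed at 14 against 8.5 weeks (3 unadjusted, DESeq2 0) and 1 rose at 14 against 3.5 weeks (26 unadjusted). For the share, 1, 0 and 0 of 289 passed (45, 7 and 30 unadjusted; beta-binomial 34, 0 and 0). DESeq2 called 22 at 8.5 against 3.5 weeks, where the median log2 change was 1.23. With 1 library left out there were 0 to 22 calls (0 without library 1 or 3 of 8.5 weeks or 2 of 14 weeks, 14 without library 1 and 22 without library 3 of 3.5 weeks). Whether the change to 8.5 weeks differed from that in brain was not tested; for the change to 14 weeks the interaction adjusted p was 0.111 for gulp1 and 1.00 for cap2.2.

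In muscle at 14 against 3.5 weeks, camera called 1 list, growth and nutrient signalling genes, a call that was lost with an estimated correlation and had 0 members passing singly. Over the 3 ages, akt2, a kinase of insulin signalling, had 14, 0 and 0 reads, fgfr1b, a growth factor receptor, 13, 3 and 0, and igf1ra, an insulin-like growth factor receptor, 7, 13 and 2. The growth hormone receptor circRNAs had 2, 18 and 6 (ghr.2), 6, 37 and 6 (ghrb.1) and 9, 10 and 6 (ghrb.2). Of these 6, 0 passed singly, over all tested or adjusted over the list alone, while as a set they were lower than other circRNAs, with a change above 0 in 2 (camera adjusted p = 0.0341; adjusted p = 0.342 with an estimated correlation). Of 16 circRNAs of sarcomere and excitation-contraction coupling genes, 0 passed at 14 weeks on either scale (camera adjusted p = 0.650), and at 8.5 weeks 1, atp2a1.3, passed over all and adjusted over the list alone (camera adjusted p = 0.162). Cytoskeleton and motors (9 circRNAs), axon guidance (5) and ubiquitin ligases (5) had 0 on both scales, as did the lists of 1 to 4, and the axon guidance and cytoskeleton lists had medians above 0 with a test pointing down.

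Brain and muscle differed in 207 of 896 circRNAs tested. On CPM scaled over all 15 libraries, flnc.2 reached 3924 ± 792 in muscle (SD, n = 6) and 103 ± 50.5 in brain (n = 9; log2 -5.27, SE 0.27, adjusted p = 6.93e-81), and ryr1b 729 and 20.3 (log2 -4.90, SE 0.38). Higher in muscle were also ttn.1 (490 reads against 1, ratio 2244, counting interval 401 to 88800), myot.2 of the Z-disc protein myotilin (at least 215-fold) and atp2a1.3 (at least 156-fold). So were rilpl1.1 (161 reads against 1, ratio 737, interval 130 to 29297) and mef2ca.1 of a muscle transcription factor (ratio 195, interval 52.2 to 1633). Higher in brain were LOC107395747 (367 reads against 0, at least 26.7-fold), bace1 (566 against 1, ratio 124, interval 22.1 to 4891) and klc1 (540 against 4, log2 5.49, SE 0.65). So were ptprz1b.1, from a phosphatase receptor of glia (at least 13.8-fold), nptn.1 of neuroplastin, a synaptic adhesion protein (at least 9.46-fold), and myo15aa (at least 7.13-fold). On the linear totals without TMM the bound was 76.3-fold for LOC107395747 and 75.4-fold for myot.2. The ratios were then 786 for ttn.1 (interval 140 to 31093), 258 for rilpl1.1, 68.1 for mef2ca.1 and 353 for bace1. CircRNAs abundant in both were eif3l, at 280 CPM in brain and 953 in muscle (log2 -1.78, SE 0.28), nsun4.1 (log2 -1.71) and LOC107387794, at 443 and 274, which did not pass (adjusted p = 0.0599). On the linear totals without TMM, eif3l and nsun4.1 did not pass (log2 -0.26 and -0.20) and LOC107387794 did (log2 2.31).

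**Figure D2:**
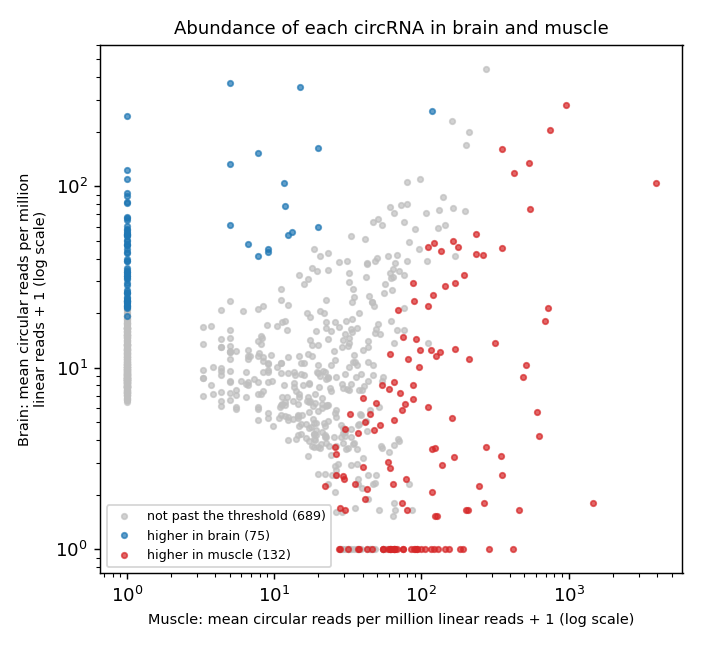
Mean circular CPM plus 1 in muscle (x axis) and brain (y axis), both log scales, 1 point per circRNA tested. Blue points are the 75 circRNAs higher in brain, red points the 132 higher in muscle and grey points the 689 that did not pass.

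Of the 20 circRNAs of sarcomere and excitation-contraction coupling genes, 14 were lower in brain, over all tested and adjusted over the list alone, among them flnc.1, ryr1b, mylk4a.1, neb.2, mybpc2b, myom2a, mypn and the calcium pump atp2a2a (log2 -1.66, SE 0.35). The set test passed (camera adjusted p = 8.39e-12; adjusted p = 0.000432 with an estimated correlation). All 35 postsynaptic circRNAs had a higher fitted level in brain and 4 passed, among them grin2ab.1 (39 reads against 0), grin2da.2 (34 against 0) and grin2da.3 (50 against 0) of NMDA receptor subunits, with 0 adjusted over the list alone. The set passed (camera adjusted p = 0.00413), though not with an estimated correlation (adjusted p = 0.10 with an estimated correlation). Among 30 circRNAs of axon guidance and adhesion genes, 5 were higher in brain, ptprz1b.1, adgrl2.1 (156 reads against 3), cadm2 (77 against 0), astn1.1 and tenm1.1, and 1 was lower, adgrl2.4. Counts adjusted over the list alone were the same (camera adjusted p = 0.0263; adjusted p = 0.233 with an estimated correlation). Of 7 growth signalling circRNAs, 4 were lower in brain on both scales, ghr.2, ghrb.1, ghrb.2 and igf1ra (camera adjusted p = 0.0297; adjusted p = 0.10 with an estimated correlation).

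Other lists did not pass as sets. Of 16 ion channel circRNAs, 3 were higher in brain (kcnc3b, ryr2a and cacna1bb) and 2 lower, both of the muscle sodium channel scn4aa (4 and 2 adjusted over the list alone; camera adjusted p = 0.648). Of 17 of the cytoskeleton and motors, 6 were lower in brain, myo5aa, ank2a, ank2b.2, dock9.1, dst and myo18a (1 higher and 6 lower adjusted over the list alone; adjusted p = 0.126). Lower in brain were also 2 of 10 from chromatin regulators (hdac9 and mllt10), 2 of 5 from RNA-binding proteins (mbnl1 and srsf7) and 1 of 11 known mammalian hosts (mbnl1). Counts adjusted over the list alone were the same, and camera adjusted p were 0.419, 0.162 and 0.648. Ubiquitin ligases had 2 of 7 lower, nedd4 and ubr3, the latter with a log2 of -1.09 that was 0.43 and did not pass on the linear totals without TMM (1 higher and 3 lower adjusted over the list alone; adjusted p = 0.355), and active zone genes 0 of 7 on both scales (0.419). Too small for a set test, the oligodendrocyte list had 1 of 3 higher in brain, enpp6.2 (231 reads against 2), on both scales. The astrocyte list had 2 of 2 lower on both scales, both of the sodium pump atp1a2a, which muscle also expresses. The fibroblast list had 0 of 3 on both scales, microglia 0 of 1 (1 adjusted over the list alone) and blood and vessel no circRNA tested. For chromatin and cytoskeleton the median was above 0 and the mean and test below, and for mammalian hosts the median and mean were above 0 and the test below.

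In all, 207 of 896 circRNAs differed in abundance, 75 higher in brain and 132 higher in muscle (307 unadjusted). The balance of directions depended on the scaling. TMM factors of the linear counts were 1.48 to 1.59 in brain and 0.479 to 0.601 in muscle, and the median log2 difference was 1.16. On the linear totals without TMM the median was 2.00 and 387 circRNAs differed, 297 higher in brain and 90 in muscle. All 75 calls higher in brain remained, as did 90 of the 132 higher in muscle, and 4 of these 132 had the opposite sign without passing. With TMM of the circular counts 298 were higher in brain and 90 in muscle. Among the listed circRNAs lower in brain, asph.1, mef2ca.2, atp2a2a, adgrl2.4, mllt10, ank2b.2, dock9.1, myo18a, srsf7, nedd4 and ubr3 did not pass on the linear totals. Without muscle library 3 of 3.5 weeks 133 differed in abundance and 18 in the share.

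The share of circular reads was also compared between tissues at each position. The circRNA of myo5aa, which encodes the vesicle motor myosin Va (chromosome 11, 1070208 to 1075896), had 62 circular and 57 linear reads in muscle, where its share was 49.7% ± 21.9 (SD, n = 6). In brain it had 0 circular beside 769 linear reads, which allows a share of up to 0.390% (adjusted p = 1.65e-20). For mapk8b, a JNK kinase, muscle had 39 circular and 154 linear reads and brain 0 and 581 (adjusted p = 4.67e-08). The share of ank2a, an ankyrin, was 11.8% in muscle and 0.0823% in brain (adjusted p = 1.96e-07), and that of rilpl1.1 30.9% and 0.505% (adjusted p = 8.55e-09). In the opposite direction, klc1 had a share of 69.5% ± 3.13 in brain (SD, n = 9) and 13.7% ± 19.2 in 5 muscle libraries with reads (log2 3.39, SE 1.09, adjusted p = 0.0477). In all, 36 of 893 shares differed, 1 higher in brain and 35 lower (96 unadjusted). The beta-binomial test called 75, of which 18 were higher in brain and 57 lower. The directions were not equally testable, as some brain-high positions had few linear reads in muscle. In muscle, 0 circular reads beside 4 linear reads allow a share of up to 75% for myo15aa. Beside 6 linear reads they allow up to 50% for nptn.1 and rbm14b.

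Linear reads of the host genes were compared between 14 and 3.5 weeks to ask whether the genes themselves changed. In brain, helz2, an interferon-inducible helicase, rose from 174 to 1044 CPM (log2 2.56, SE 0.41, adjusted p = 0.00225) and usp54b from 911 to 2115 (log2 1.21, SE 0.21, adjusted p = 0.00291). Also higher were the Ras pathway genes rasgrf2 (log2 1.13) and cnksr2 (0.93), the kinase gene prkd1 (1.22), lrmp (1.35) and mprip (0.69). Lower at 14 weeks were genes of contractile and matrix proteins, among them 7 of the 16 hosts of the sarcomere list. The reads of atp2a1 fell from 3732 to 54.8 CPM (log2 -6.14, SE 0.76, adjusted p = 0.000259), mybpc2b by a log2 of -4.66, postn, which encodes the matrix protein periostin, by -4.33, ttn.1 by -4.13 and mylk4a by -3.95. Of 1232 hosts, 10 rose and 26 fell (172 unadjusted). Left-out libraries gave 13 to 40 calls, with 13 without library 3 and 14 without library 2 of 14 weeks, and 14 without library 3 and 23 without library 2 of 3.5 weeks. The sarcomere list took 4081, 13976 and 13436 linear CPM in brain libraries 1, 2 and 3 of 3.5 weeks and 3047 to 3866 in the older ones. The fibroblast list took 766, 2637 and 2292 in those 3 libraries and 606 to 773 later, with 2 of 3 hosts lower. In a fit without libraries 2 and 3, chosen after seeing the data, library 1 alone stood for 3.5 weeks. The log2 changes were then 1.63 for usp54b, 2.38 for helz2 and -3.81 for atp2a1. The log2 change of mybpc2b was -1.86 and that of ttn.1 -1.25 in that fit.

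**Figure D3:**
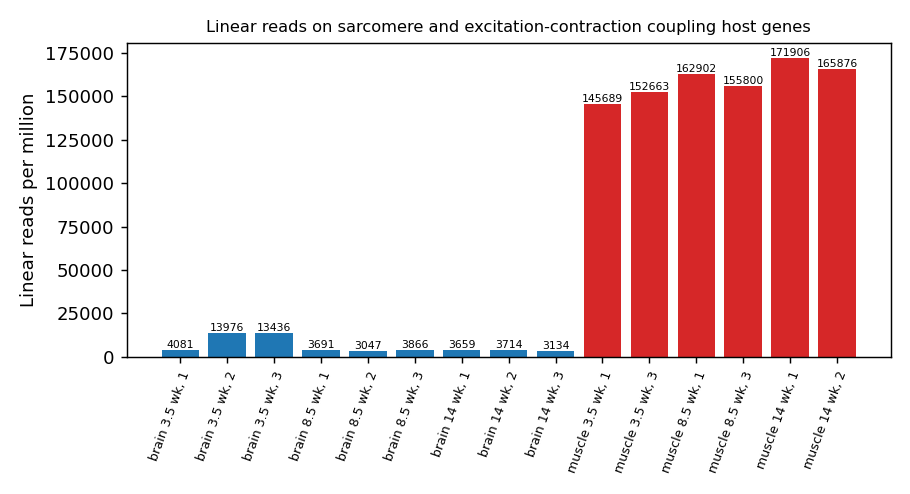
Linear CPM on the 16 hosts of the sarcomere and excitation-contraction coupling list (y axis, from 0) for each brain and muscle library (bars, x axis). Brain libraries 2 and 3 of 3.5 weeks stand at 13976 and 13436, the other brain libraries between 3047 and 4081, and muscle libraries between 145689 and 171906.

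In muscle, the linear reads of rps15, a ribosomal protein gene, fell from 64836 CPM at 3.5 weeks to 20404 at 14 weeks (log2 -1.67, SE 0.18, adjusted p = 9.38e-10). Those of hspa8, the constitutive heat shock chaperone, fell from 79938 to 25242 (log2 -1.66, SE 0.19, adjusted p = 1.19e-09). The arginine synthesis gene ass1 (log2 -2.28, adjusted p = 6.19e-08), the peptidase gene mme (-1.33) and filip1l (-1.19) were lower too. Among the genes that rose were helz2, from 56.1 to 369 CPM (log2 2.63, SE 0.69, adjusted p = 0.0152), the neurotrophin receptor gene ntrk3 (4.73), the lysosomal membrane gene lamp2 (1.91), nisch (1.84), ank2a (1.46), the splicing factor gene mbnl1 (1.43) and cox4i2 (1.19), a cytochrome c oxidase subunit. Of 938 hosts, 12 rose and 17 fell (133 unadjusted). Left-out libraries gave 19 to 32 calls, with 19 without library 1 of 3.5 weeks or library 2 of 14 weeks.

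Changes of circular reads between 3.5 and 14 weeks were correlated with those of linear reads at the same position, with Pearson r = 0.157 and Spearman rho = 0.158 across 638 circRNAs in brain. In muscle they were 0.201 and 0.275 across 289. Between 3.5 and 8.5 weeks they were 0.212 and 0.255 in brain and 0.301 and 0.357 in muscle. With 30 or more reads per circRNA, r for that step was 0.406 in brain and 0.436 in muscle. CircRNAs are not independent replicates, so no p is given. The median log2 change was 0.34 for circular and 0.03 for linear reads in brain, and 0.77 and 0.01 in muscle. Both were scaled to the linear counts, which holds the linear median near 0. The medians therefore cannot show that linear reads stayed level.

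The authors' deposited tables listed a p-value for neighbouring ages. For brain at 8.5 against 3.5 weeks, the authors' deposited table had 251 circRNAs, 37 (14.7%) with p under 0.05 and none after Benjamini-Hochberg adjustment. The authors' deposited table was led by xpr1a, a phosphate exporter gene (p = 0.000751), LOC107390307.1, LOC107395747 and ptprg.1 (adjusted 0.154 for these). For brain at 14 against 8.5 weeks, the authors' deposited table had 296 circRNAs, 18 (6.08%) of them under 0.05 and none after adjustment. The authors' deposited table was led there by grin2a, an NMDA receptor gene (p = 0.00751, adjusted 0.649). For muscle at 8.5 against 3.5 weeks, 58 of the 228 p-values in the authors' deposited table (25.4%) were under 0.05 and 7 after adjustment. It was led by cap2.2 and mme (adjusted 0.0148 each), then LOC107395701, cdc73.1 and neb.2 (0.0490 each). For muscle at 14 against 8.5 weeks, 18 of the 253 in the authors' deposited table (7.11%) were under 0.05 and none after adjustment. Smallest in the authors' deposited table was atf7, a transcription factor gene (p = 0.00175, adjusted 0.443).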

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

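The fits without brain libraries 2 and 3 of 3.5 weeks, without the positions with the most linear reads, on the linear totals without TMM, and the gene lists at 8.5 weeks were chosen after seeing the data. For named circRNAs and hosts, 1868 alternative values kept direction and side of the threshold, 172 lost the threshold and 31 gained it. The named include circRNAs that did not pass as reported, for which failing again counted as kept. The tally therefore does not measure how well the calls held. With TMM of the circular counts, brain abundance had 0 calls at 8.5 against 3.5 weeks, 0 at 14 against 3.5 weeks and 0 for any age, and muscle 2 at 14 against 3.5 weeks. Between tissues 388 circRNAs differed (298 higher in brain and 90 lower, beside 75 and 132), and on the linear totals without TMM 387. No filter gave 0 in brain and 2 in muscle at 14 against 3.5 weeks, 0 for any age, and 0 muscle shares at 8.5 weeks, where fewer reads per circRNA and more tests enter. A minimum of 30 reads gave 2 in brain at 8.5 weeks, 1 brain share at 14 against 3.5 weeks, 7 in muscle at 8.5 weeks, 10 and 3 muscle shares at 8.5 and 14 against 3.5 weeks, 0 for any age. It gave correlations of circular with linear change of 0.331 in brain and 0.274 in muscle. DESeq2 gave 0 in brain and 2 in muscle at 14 against 3.5 weeks, 22 in muscle at 8.5 weeks and 0 for any age, which was also 0 with DESeq2 size factors. The beta-binomial test called 34 muscle shares at 8.5 weeks and 75 between tissues (18 higher and 57 lower). Without brain libraries 2 and 3 of 3.5 weeks, 2 circRNAs passed at 14 against 3.5 weeks, 0 for any age and 2 of the brain hosts. The slope of detected brain circRNAs was -0.227 per week (exact permutation p = 0.943), and the tissue difference of the total share was 0.568 points (exact p = 0.0867), where fewer brain libraries of 3.5 weeks shift the mix of ages; averaged over the ages it was 0.430 (exact p = 0.113). That difference was 0.491 (exact permutation p = 0.095) with linear reads once per host, -0.478 (p = 0.165) without the positions among the 10 with the most linear reads in either tissue, and -0.288 (p = 0.359) when each tissue lost its own 10. With an estimated correlation, adjusted p was 0.342 for growth signalling in muscle and 0.233, 0.10 and 0.10 for axon guidance, growth signalling and postsynaptic genes between tissues. With 1 circRNA per host, growth signalling between tissues had 0.135 and ion channels in brain reversed (0.949). The cause of these changes was not tested. When 1 library was left out, calls ranged from 0 to 4 in brain abundance at 8.5 weeks (4 without library 3 of 3.5 weeks). They ranged from 0 to 1 at 14 against 3.5 weeks and 0 to 2 for any age (0 without library 1 or 2 of 3.5 or 8.5 weeks). In muscle abundance they ranged from 0 to 22 at 8.5 weeks and 0 to 4 at 14 against 3.5 weeks (0 without library 1 or 3 of 8.5 weeks, or 1 or 2 of 14 weeks), and from 0 to 5 for muscle shares at 8.5 weeks (5 without library 2 of 14 weeks). Between tissues there were 133 to 204 and 18 to 39 calls for abundance and share (133 and 18 without muscle library 3 of 3.5 weeks; 23 without muscle library 2 of 14 weeks), and 0 to 2 for the tissue difference of the change (2 without muscle library 1 of 14 weeks). Host calls were 13 to 40 in brain (13 without library 3 and 14 without library 2 of 14 weeks; 14 without library 3 and 23 without library 2 of 3.5 weeks) and 19 to 32 in muscle. Slopes ranged from 0.0373 to 0.0725 (brain share), 0.0610 to 3.00 (brain circRNAs detected), 0.0272 to 0.137 (muscle share) and 10.6 to 14.3 (muscle circRNAs detected), and the tissue difference of the total share from 0.281 to 0.681, or 0.355 to 0.566 averaged over the ages. Where 1 library of an age was left, it was assumed to vary like the others. The labels do not say whether the replicate numbers pair the libraries. Deviations of same-numbered libraries from their group means had correlations of -0.178 to 0.0951. With 2 or 3 libraries per group, such values cannot decide whether the numbers name shared animals. With the replicate block, brain calls were 0 at 8.5 and 0 at 14 against 3.5 weeks and 0 for any age, muscle calls 9 at 8.5 weeks with 6 shares, tissue calls 89 with 7 shares, and the tissue difference of the total share 0.605 (exact permutation p = 0.0625). The muscle values with the block used only the libraries of 3.5 and 8.5 weeks. The tissue values used only libraries with a partner of the same age and number. The effect of the block was not told apart from that of fewer libraries. Depth limits single circRNAs: most held few reads.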

Other observations

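The comparison of hosts between tissues, the test of an exchanged library, the test of deeper libraries, both tests of a ceiling and all splits of the samples were chosen after the results were seen. Some host genes changed in the same direction in brain and muscle between 3.5 and 14 weeks. Among 931 hosts tested in both tissues, helz2 and LOC107394856 were higher at 14 weeks in both, where 7 and 11 calls per tissue would share 0.0827 if independent. Lower in both were the chaperone gene hspa8, the sodium pump gene atp1a2a, the titin gene ttn.1 and LOC107384395, 4 of 25 and 16 calls, where independent lists would share 0.430. In brain, hspa8, singled out after its values were seen, fell from 47563 to 29811 linear CPM (log2 -0.67, SE 0.15, edgeR adjusted p = 0.0165; -0.49, SE 0.21, adjusted p = 0.640 without libraries 2 and 3 of 3.5 weeks), beside 79938 to 25242 in muscle. The gene atp1a2a went from 698 to 92.7 CPM in brain and from 21724 to 13737 in muscle. No library is shared between the tissues, but 3 of the 4 shared lower genes, atp1a2a, ttn.1 and LOC107384395, are far higher in muscle, and their fall in brain moves with the muscle transcripts of the young brain libraries.

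Muscle transcripts were high in brain libraries 2 and 3 of 3.5 weeks, which were singled out after their values were seen. A choice of genes that are low in the other brain libraries can favour an excess in these 2. Of the 30 host genes chosen for a high level in muscle and a low one in other brain libraries, 26 in library 2 and 25 in library 3 exceeded the highest of the 7 other brain libraries, with a median excess of 6.46% and 3.71% of the muscle level, while library 1 exceeded the 6 older brain libraries in 9 (0.493%). The linear profiles of both libraries remained nearer to brain than to muscle (difference of r at most -0.584), which argues against an exchanged library. Without them the median of 23 called falls that were still tested went from a log2 of -3.22 to -1.05, mybpc2b from -4.66 (SE 0.66) to -1.86 (SE 0.56) and ttn.1 from -4.13 (SE 0.69) to -1.25 (SE 0.60), while the 10 rises went from 1.17 to 1.27 and lost 9 calls with fewer libraries. Muscle RNA carried into these 2 samples is a candidate explanation for part of the falls, and age remains open. The log2 change of atp2a1 went from -6.14 (SE 0.76) to -3.81 (SE 0.54) without them. Library 1 alone then stands for 3.5 weeks, and it exceeded the 6 older libraries in 9 of the 30 genes. The remaining fall of atp2a1 therefore cannot tell muscle RNA from age.

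Circular reads were more frequent in both muscle libraries of 8.5 weeks than in both of 3.5 weeks. The lowest share at 8.5 weeks over the highest at 3.5 weeks was 2.40 without the 10 most-read circRNAs and 2.05 without the 10 positions with the most linear reads, which argues against a few circRNAs or a few linear positions as the whole cause. The linear totals did not explain it either, as their ratio was 0.863 while that of the circular totals was 2.02. Age may account for the rise, but with 2 libraries per age it was not tested apart from library preparation.

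Linear counts appear to be capped at some positions, which were singled out after their values were seen. In muscle, LOC107389481 (chromosome 9, 33385798 to 33386509) had 7824 to 7897 linear reads in all 6 libraries, with a variance over mean of 0.0846, less than counting noise gives. A circRNA with no host on scaffold scf223 (8529 to 10767) had 3605 to 3823 linear reads in all 15 libraries, with 0.00868 of the variance over mean that scaling to the library totals gives. A ceiling on the counted depth may be the cause in both, and would raise the circular share of the most expressed positions. No biological explanation was tested.

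Other splits of the samples were set beside each count of calls. For circRNA abundance between tissues 1 of 100 splits, the real one, gave as many calls (207, highest other 106), and for the share 2 of 100 (36, highest other 43). Both fractions are under 0.05. However, 1 other split called more shares than the real one, and tissue and age were shuffled together. The number of share calls therefore does not set tissue apart. The highest other splits point to structure among the samples. For any age in brain, 5 of 100 splits gave as many abundance calls (1, highest other 2), so chance was not excluded. With 0 share calls for any age (highest other 0), 100 of 100 splits gave as many by construction, which decides nothing. For pairs of ages in brain, 10 splits are too few for a share under 0.05: abundance calls were 1 (highest other 1) at 8.5 against 3.5 weeks, 0 (0) at 14 against 8.5 weeks and 1 (0) at 14 against 3.5 weeks, share calls 0 (0) at each, and host calls 36 (2).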
